A study of Mus musculus with 2 samples.

How the data were processed

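Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse embryonic stem cells that carried YFP-tagged H2A.Z, either wild type or K3R3. H2A.Z is a variant of histone H2A found mainly at promoters and enhancers. In K3R3 the 3 lysines at positions 119, 120 and 123 of its C-terminal tail are replaced by arginines. Per the labels' protocols, the transgenes were driven by a doxycycline-inducible promoter and induced with 1 µg/ml doxycycline. YFP-positive cells were sorted, and short hairpins against the 3′ UTR of the endogenous transcript lowered the untagged protein. The labels give the strain as V6.5, and the protocol describes the transgenic lines as KH2 embryonic stem cells. The antibody listed is Abcam ab290, an antibody against GFP that also recognises YFP, so the tagged protein was immunoprecipitated. Chromatin was sonicated for 30 cycles of 30 s on and 30 s off. Fragments of 200 to 400 bp were selected and amplified for 19 cycles. There was 1 library per group, so no difference between the groups has a replicate check and no p-value is given.

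The authors deposited 2 lists of enriched regions per library, named in the track lines by the thresholds 1e-09 (looser) and 1e-12 (stricter), 4 lists in all. Each list held only a chromosome, a start and an end per region, with no height, fold enrichment, score or p-value, and each list came from a single library. Per the submitters' processing notes, Bowtie 0.12.3, bedtools and the mouse genome build mm9 were used. The track lines of both libraries carry the same tag, LSWCE, whose meaning is not stated. The program that called the regions, its filters and the control are not given in the sources used here. Coordinates were multiples of 25 bp and the smallest gap between neighbouring regions was 225 bp in every list. Read depth is unknown from region lists, so list lengths were not adjusted for depth and no interval that needs it is given. The lists of a library were not nested. Of 97146 stricter wild-type regions, 5962 (6.14%) overlapped no looser wild-type region, and of 110435 stricter K3R3 regions, 7518 (6.81%) overlapped no looser K3R3 region. A region can therefore be missing from a looser list and still pass the stricter threshold.

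The looser lists were the main data. A region was called shared when it overlapped a region of the other library by at least 1 bp. Shares are given with 95% Wilson intervals, which cover counting error only and treat regions as independent. For comparison, the wild-type regions were moved 100 times by a random circular shift within each chromosome. The Jaccard index is the length covered in both libraries over the length covered in either. At shared places, overlapping regions of both libraries were grouped into clusters, and the total width of the wild-type regions in a cluster was divided by that of the K3R3 regions. A library-specific region was defined as a region of the stricter list of a library that overlapped no region in the looser list of the other. Chromosomes were compared by region counts and covered length, and in 10 Mb windows with at least 50 K3R3 regions. Regions were named by a fixed rule, namely the 5 widest regions of each library and the 5 widest library-specific regions of each library. Coordinates are printed 1-based in mm9. The main comparisons, the rule for named regions and alternatives for the threshold, the overlap, the joining of neighbouring regions and list length were fixed before the data were examined. Region counts and covered length per chromosome were among these comparisons. The grouping of shared regions into clusters, the width classes and the 10 Mb windows were chosen afterwards. So were several alternatives, namely leaving out chromosomes 6 and 8, using both lists of the other library together, counting library-specific regions in lists of equal length, and setting covered length and joined regions against the ratio of region counts on chromosomes 6 and 8.

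Distances to transcription start sites and 12 gene lists had also been planned. They were not run, because the gene table at hand is of GRCm38 and the regions are in mm9, so no region was assigned to a gene, exon, intron or UTR. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The interval functions were checked against bedtools 2.31.1 on the looser lists. They were also tested on simulated data made from the 99812 wild-type regions, where the share of kept regions (76.9%) and all 19152 added regions were recovered.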

Results

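The data consisted of regions enriched for YFP-tagged H2A.Z in mouse embryonic stem cells expressing the wild-type histone variant or K3R3, in which 3 C-terminal lysines, known as sites of mono-ubiquitylation, are arginines. The series addresses how mono-ubiquitylation of H2A.Z acts in embryonic stem cell chromatin, and this comparison asks whether the mutant histone occupies the same places as the wild type. There was 1 library per group, so the values compare 2 libraries, with no replicate check and no p-value. Read depth is unknown, and intervals cover counting error only. The looser lists (threshold 1e-09) held 99812 wild-type and 114028 K3R3 regions. The stricter lists (1e-12) held 97146 and 110435.

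K3R3 gave more regions than wild-type H2A.Z on every autosome except 6 and 8 and on X. At shared places its regions were slightly wider on the autosomes other than 6 and 8. The K3R3 list was 1.14 times as long as the wild-type list and covered 53.9 Mb against 50.3 Mb, a ratio of 1.07. Without chromosomes 6 and 8, where the wild-type library had the excess, the ratios rose to 1.21 for regions and 1.14 for length. Median width was 325 bp in both libraries, with quartiles of 200 and 650 bp in the wild type and 200 and 600 bp in K3R3. Broad regions of at least 2000 bp numbered 1961 in the wild type and 1784 in K3R3. Outside chromosomes 6 and 8 the order turned, with 1558 wild-type and 1580 K3R3 broad regions. In the stricter lists the wild type had more broad regions in either case, 1498 against 1229 on all chromosomes and 1176 against 1090 outside chromosomes 6 and 8. Regions under 200 bp made up 23.5% of the wild-type and 23.6% of the K3R3 list.

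Most regions occupied by wild-type H2A.Z were also occupied by K3R3. Of the wild-type regions, 81412 (81.6%, 95% Wilson interval 81.3 to 81.8) overlapped a K3R3 region, and of the K3R3 regions, 81978 (71.9%, 71.6 to 72.2) overlapped a wild-type region. Random placement gave 4.36% (range 3.92 to 5.00 over 100 shifts) and 3.85% (3.47 to 4.38). Regions of both libraries covered 40.8 Mb in common, a Jaccard index of 0.643 against 0.0110 for random placement. The shifts took no account of gene density or mappable sequence. Random placement is therefore a low bar, which other lists from such cells could also pass. The numbers of shared regions were nearly the same, so the gap between the 2 shares largely reflects the different list lengths. With equal numbers of regions taken from both libraries, widest first, the shares were 77.3% and 77.6%. Equal list lengths bring them close by construction.

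Sharing rose with width in both libraries. Of regions of at least 2000 bp, 97.7% (96.9 to 98.2) of the wild-type and 98.5% (97.8 to 99.0) of the K3R3 regions were shared. Between 400 and 800 bp the shares were 89.3% and 86.1%. Below 100 bp they were 46.5% (45.4 to 47.7) in the wild type and 27.3% (26.3 to 28.2) in K3R3. Shared regions had a median width of 375 bp in the wild type and 400 bp in K3R3, whereas regions without a partner had medians of 200 and 175 bp.

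**Figure D1:**
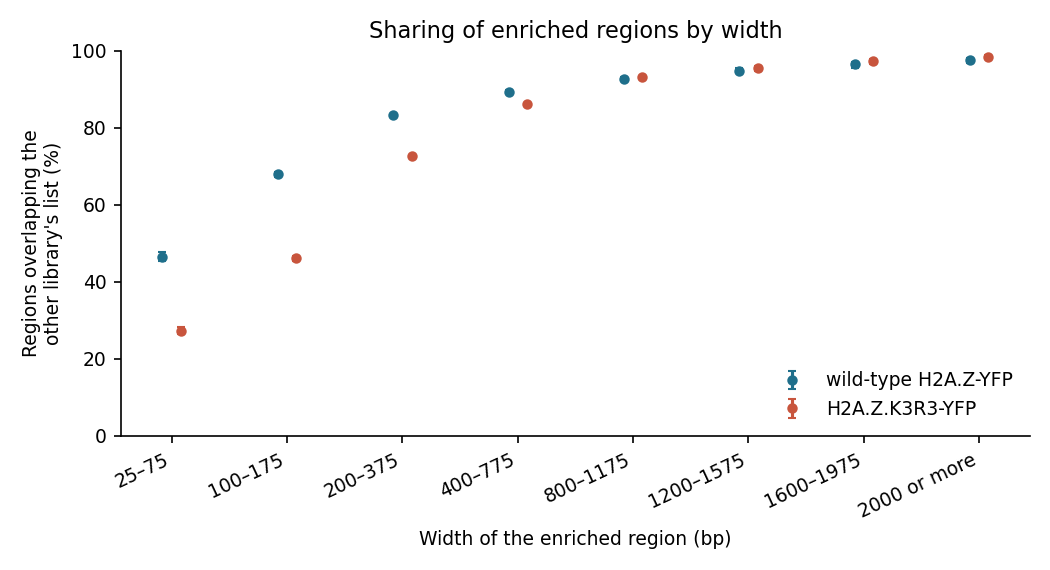
Share of regions in the looser list of each library that overlap a region of the other library (percent, y axis) by region width (bp, x axis); points are shares and bars 95% Wilson intervals. The shares climb from 46.5% (wild type) and 27.3% (K3R3) below 100 bp to 97.7% and 98.5% at 2000 bp or more.

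Where both proteins were found, the midpoints of the regions mostly lay close together. Overlapping regions formed 80096 shared clusters, of which 77087 held a single region of each library. In these, the midpoints were a median of 12.5 bp apart, and 91.1% lay within 100 bp. The clusters were picked for overlap, so small distances between narrow regions are partly built in. A reciprocal overlap of 50% held for 70.5% of wild-type and 61.7% of K3R3 regions, against 81.6% and 71.9% at 1 bp. Over all clusters the widths in the 2 libraries had a Spearman rho of 0.887 across clusters, which are not independent replicates. The log2 ratio of wild-type to K3R3 width had a mean of -0.09 and a median of 0.00 (quartiles -0.28 and 0.14). K3R3 was wider in 49.5% of clusters, the wild type in 37.1%, and 13.5% had equal widths. On chromosomes 6 and 8 the wild type was wider in 67.4% of 10406 clusters, with a mean log2 ratio of 0.28, against -0.15 on the other chromosomes. On X neither library was clearly wider, with the wild type wider in 43.9% of clusters and K3R3 in 43.0%, and a mean log2 ratio of -0.019. A wild-type region was split into several K3R3 regions in 1748 clusters, and the reverse occurred in 1220. Most of this gap lay on chromosomes 6 and 8, with 424 and 49 such clusters, and elsewhere the counts were 1324 and 1171.

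The 5 widest regions of the wild type lay on chromosomes 5, 8, 15, 17 and 9, and K3R3 covered most of each. The widest was 7650 bp long, on chromosome 5 from 124525576 to 124533225, and all of it was also enriched in K3R3. There the K3R3 region went on to 124535600 and was the widest of that library, with 10025 bp, of which 95.3% was covered by 3 wild-type regions. In the stricter K3R3 list the same domain fell into pieces, the longest of 5425 bp. On chromosome 8 a wild-type region of 7625 bp (73266026 to 73273650) was covered to 83.6% in K3R3. On chromosome 15 the wild-type region of 7500 bp (76006901 to 76014400) lay wholly within a K3R3 region of 7600 bp. The wild-type regions on chromosome 17 (25516176 to 25523650) and chromosome 9 (108011951 to 108018850) were covered to 96.0% and 99.3%. Of the other 3 regions among the 5 widest of K3R3, those on chromosome 5 (111701726 to 111709225, 7500 bp) and chromosome 8 (13220526 to 13227525, 7000 bp) were covered to 84.0% and 92.9% by wild-type regions. The last, on chromosome 18, had no wild-type counterpart.

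The longer K3R3 lists held more regions of their own than the wild-type lists. Of the stricter K3R3 regions, 28348 (25.7%, 25.4 to 25.9) overlapped no looser wild-type region, and of the stricter wild-type regions, 17308 (17.8%, 17.6 to 18.1) overlapped no looser K3R3 region, a ratio of 1.64. Outside chromosomes 6 and 8 the counts were 27182 and 12612, a ratio of 2.16. On chromosomes 6 and 8 the order turned, with 4696 wild-type-only and 1166 K3R3-only regions. Library-specific regions were narrow, with a median width of 200 bp in both libraries. Those of at least 1000 bp numbered 587 in the wild type and 462 in K3R3, but 411 and 456 without chromosomes 6 and 8. When both lists of the other library had to lack the region, 14240 wild-type-only and 25538 K3R3-only regions remained. Of these, only 392 and 324 were at least 1000 bp wide, on all chromosomes. With lists of equal length, widest regions first, there were 20883 K3R3-only and 20228 wild-type-only regions, or 17710 and 16066 without chromosomes 6 and 8. Most shared clusters held a single region of each library, so equal lengths bring such counts close whatever caused the excess. These counts therefore do not bear on its cause. Region lists do not give read depth, immunoprecipitation efficiency or the amount of tagged protein. Each can change list length, so the excess cannot be assigned to the mutation or to any of these.

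The widest library-specific region was a K3R3 domain of 6875 bp on chromosome 18 (63811326 to 63818200). It was 6925 bp long in the looser list, and neither wild-type list held a region within 10 kb of it. The second was a K3R3 region of 4475 bp on chromosome 10 (58755026 to 58759500). It had no wild-type region over it in either list, although a stricter wild-type region of 675 bp (58753926 to 58754600) lay beside it. A K3R3-only region of 3250 bp on chromosome 19 (3436251 to 3439500) also had no wild-type region over it, but 3 looser wild-type regions lay within 1000 bp of it. Its looser K3R3 form was 3775 bp long and overlapped a wild-type region of 225 bp (3435801 to 3436025). The K3R3 regions on chromosome 10 (74399201 to 74402925, 3725 bp) and chromosome 12 (113509301 to 113512600, 3300 bp) were covered to 33.6% and 44.7% by the stricter wild-type list, and the former was itself absent from the looser K3R3 list. Among wild-type-only regions, those on chromosome 17 (29905201 to 29908275) and chromosome 4 (151634851 to 151637925), each of 3075 bp, had no K3R3 region over them in either list. The other 3, on chromosome 8 (122863426 to 122866550), chromosome 5 (115096401 to 115099500) and chromosome 12 (114333326 to 114336350), were covered to 17.6%, 36.3% and 38.8% by the stricter K3R3 list.

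**Figure D2:**
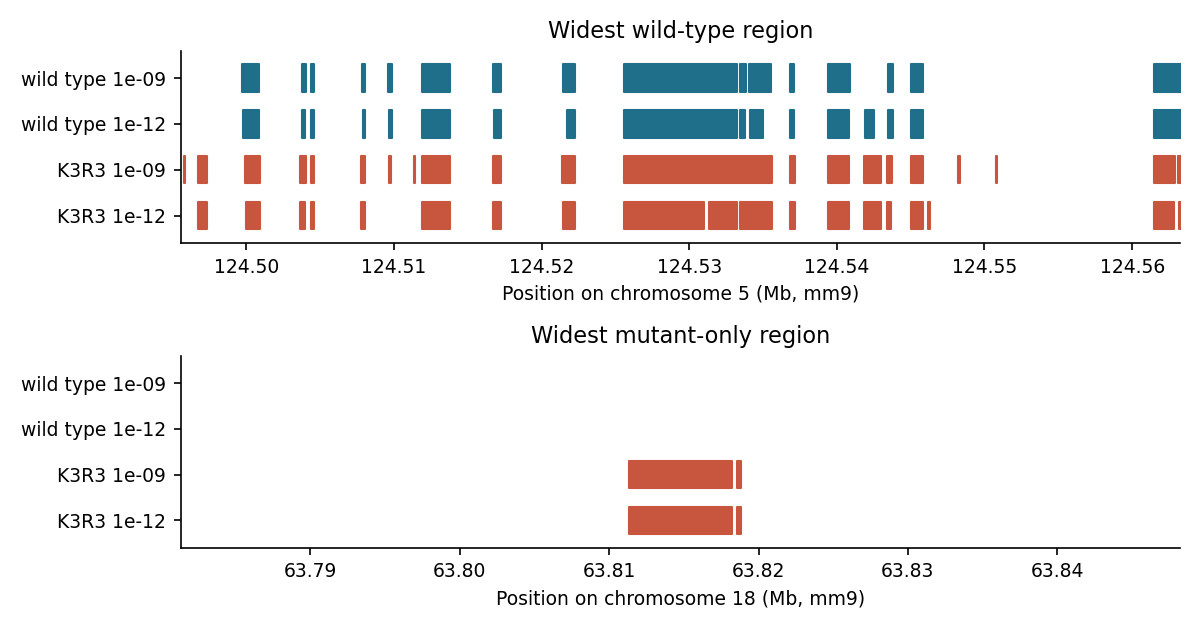
Enriched regions (bars) in the looser (1e-09) and stricter (1e-12) list of each library along mm9 (x axis, Mb), with 30 kb on either side of the widest wild-type region on chromosome 5 and of the widest K3R3-only region on chromosome 18. Both libraries fill the chromosome 5 domain, while the wild-type rows are empty around the 6875 bp chromosome 18 domain.

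Region counts by chromosome set chromosomes 6 and 8 apart from the rest. Chromosome 6 held 7626 wild-type and 5936 K3R3 regions, a ratio of 1.28, and chromosome 8 held 7819 and 6288, a ratio of 1.24. On the other 17 autosomes the ratio of wild-type to K3R3 regions ranged from 0.775 (chromosome 13) to 0.867 (chromosome 11). Covered length gave 1.37 and 1.40 on chromosomes 6 and 8, and 0.834 to 0.921 on the other autosomes. Wild-type-only regions made up 31.6% (30.5 to 32.6) of the stricter wild-type regions on chromosome 6 and 30.7% (29.6 to 31.7) on chromosome 8, against 14.0% to 16.5% elsewhere on the autosomes. K3R3-only regions made up 9.82% (9.08 to 10.6) and 10.0% (9.30 to 10.8), against 24.8% to 30.6%.

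**Figure D3:**
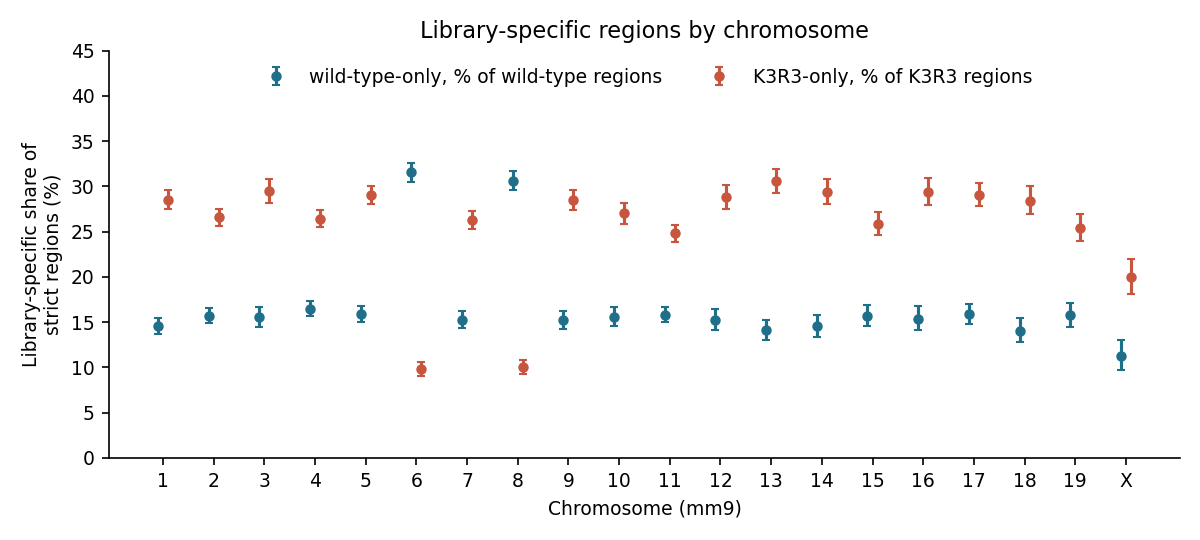
Library-specific share of the stricter regions of each library (percent, y axis) on each chromosome (x axis); points are shares and bars 95% Wilson intervals. Chromosomes 6 and 8 stand at 31.6% and 30.7% for wild-type-only and 9.82% and 10.0% for K3R3-only regions, the reverse of the order on every other chromosome.

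The wild-type excess held in every 10 Mb window of chromosomes 6 and 8 with at least 50 K3R3 regions. The ratio of wild-type to K3R3 regions was 1.16 to 1.42 in the 28 windows of chromosomes 6 and 8, and 0.601 to 0.988 in the 223 windows of the other autosomes, which had a mean of 0.813 (SD 0.065 over windows).

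**Figure D4:**
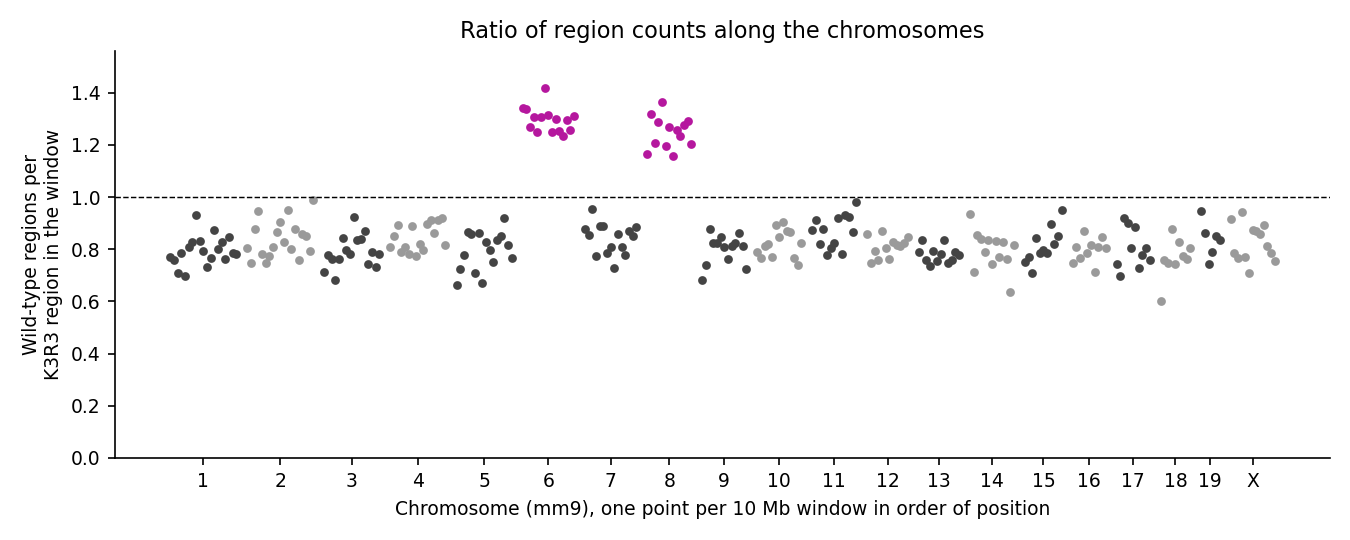
Ratio of wild-type to K3R3 regions in the looser lists (y axis) in 10 Mb windows with at least 50 K3R3 regions, in order of position along each chromosome (x axis, mm9); each point is a window, and the dashed line marks a ratio of 1. The 28 windows of chromosomes 6 and 8 (coloured) lie at 1.16 to 1.42, above the line, and the 223 windows of the other autosomes lie below it.

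The X chromosome was sparse in called regions in both libraries, which need not mean low occupancy. It held 1532 wild-type regions (1.53% of the list, 1.46 to 1.61) and 1826 K3R3 regions (1.60%, 1.53 to 1.68). These are 9.20 and 11.0 regions per Mb up to the last region, where the autosomes other than 6 and 8 held at least 25.8 and 32.2. Outside chromosomes 6 and 8 the order of the shares turned, with 1.82% in the wild type and 1.79% in K3R3. Chromosome Y had 2 K3R3 regions and no wild-type region, too few to compare.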

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

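K3R3 had more regions, more covered length and more library-specific regions under each alternative run for these. In each it was also wider on average at shared places over the chromosomes used. With lists of equal length there were 20228 wild-type-only and 20883 K3R3-only regions, but equal lengths bring such counts close by construction. The wild type had the larger share of shared regions except with equal numbers of regions, which bring the shares close by construction. No paired analysis was possible because each group had 1 library. The planned distances to transcription start sites and gene lists were not run, and read depth, which affects how many narrow regions can be called, is unknown. Leaving out chromosomes 6 and 8 and using both lists of the other library, and equal lengths for library-specific regions, were chosen after seeing the data, as were the joined-region and covered-length ratios for those chromosomes. The cause of the shifts below was not tested. Values are for wild type, then K3R3. The stricter lists covered 46.1 and 48.6 Mb, had 82.1% and 73.0% of regions shared, 1.40% and 1.43% of regions on X, a Jaccard index of 0.647, a mean log2 width ratio of -0.069, and a width rho of 0.874. Stricter regions against the looser list of the other gave 82.2% and 74.3% shared. Joining regions within 1000 bp gave 59.8 and 65.5 Mb, 83.9% and 74.1% shared, and a Jaccard index of 0.627. Requiring 50% of the region to be covered gave 78.3% and 67.3%, a reciprocal overlap of 50% 70.5% and 61.7%, and a distance of up to 1000 bp 86.9% and 78.3%. Equal numbers of regions gave 77.3% and 77.6% and a Jaccard index of 0.646. Both lists of the other library gave 84.2% and 73.8%. Without chromosomes 6 and 8, 42.4 and 48.1 Mb were covered, 84.1% and 69.9% of regions were shared, 1.82% and 1.79% lay on X, the Jaccard index was 0.646, the mean log2 width ratio -0.15 and the width rho 0.892. With a single region of each library per cluster the mean log2 width ratio was -0.10 and the rho 0.883. The wild-type to K3R3 ratio on chromosomes 6 and 8 was 1.30 and 1.27 in the stricter lists, 1.24 and 1.21 after joining, and 1.37 and 1.40 by covered length. The order of the shares on X turned without chromosomes 6 and 8. Counts of regions and of library-specific regions stayed within 1.5 times the reported ones, except the 17710 K3R3-only regions (16066 wild-type-only) with equal lengths and without chromosomes 6 and 8.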

Other observations

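The tests on chromosomes 6 and 8 were chosen after the result was seen, as were the comparison of covered length in 1 Mb windows, and the widths and comparable windows around the chromosome 18 domain. The share of K3R3-only regions around that domain and the test of the calling threshold were fixed before their results were seen.

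Both proteins were concentrated in the same stretches of the genome. Over 2556 windows of 1 Mb, the covered length in the 2 libraries had a Spearman rho of 0.989 across windows, which are not independent replicates, and 14 of the 20 densest windows were the same in both. The densest in K3R3 was on chromosome 2 between 167 and 168 Mb, with 202 kb covered in K3R3 and 195 kb in the wild type. Chromosome 10 between 79 and 80 Mb followed, with 194 and 184 kb. In the wild type the first 3 places went to neighbouring windows on chromosome 8 from 122 to 125 Mb, with 267, 245 and 210 kb, against 180, 190 and 153 kb in K3R3. Chromosome 8 held 7 of the 20 densest windows in the wild type and 3 in K3R3. K3R3 covered more than the wild type on chromosome 12 between 113 and 114 Mb, with 171 kb against 127 kb, and on chromosome 17 between 27 and 28 Mb, with 172 kb against 140 kb.

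The wild-type excess on chromosomes 6 and 8 ran along both chromosomes. In their 28 windows of 10 Mb the lowest ratio of wild-type to K3R3 regions was 1.16. The highest of 223 windows on the other autosomes was 0.988, which argues against a few dense loci. The 11 other autosomes at least as rich in K3R3 regions as chromosome 6 had ratios of at most 0.867, which argues against region density. By wild-type regions per Mb, only chromosome 11 (61.1) was as rich as chromosomes 6 and 8 (51.0 and 59.4). Its ratio was 0.867, so by that measure the comparison rests on a single chromosome. The mean log2 ratio of wild-type to K3R3 width at shared places was at most 0.19 in windows of X, where K3R3 had more regions. It was at most 0.18 in windows of the other autosomes, and at least 0.21 in all 28 windows of chromosomes 6 and 8. This is consistent with a difference in copies of chromosomes 6 and 8 between the 2 cell lines, a hypothesis, and gain of chromosome 8 is a known change in cultured mouse embryonic stem cells. Region lists cannot tell a gain in the wild-type line from a loss in the K3R3 line, and an effect of the mutation on H2A.Z over these whole chromosomes stays open, as untested.

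A K3R3-only domain of 6875 bp on chromosome 18 was the widest library-specific region. Of 22 stricter K3R3 regions within 500 kb on either side, 12 (54.5%, 34.7 to 73.1) were K3R3-only, against 28.2% on the rest of the chromosome, and 5 of 392 comparable windows of 1 Mb (1.28%) reached this share. The 392 windows were not picked for holding such a domain, as this megabase was, so they are not a like baseline. The 12 regions include a K3R3 region of 250 bp (63818576 to 63818825) right beside the domain. By the share of 54.5% alone, the test fixed beforehand spoke for a copy gain of the surrounding megabase in the K3R3 line. The widths, examined only afterwards, did not show it: of 11 shared clusters 4 were wider in K3R3 and 4 in the wild type, and the mean log2 ratio was 0.17 (SD 0.67) against -0.15 on the rest of the chromosome, where a gain in K3R3 would lower it. With 11 clusters the widths decide nothing, and a copy gain, an insertion of the lentiviral constructs nearby and an effect of the mutation all stay open, the last 2 untested.

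Regions without a partner passed the stricter threshold less often than shared ones. Of looser regions without a partner, 70.7% of the wild-type (70.0 to 71.3) and 70.7% of the K3R3 regions (70.2 to 71.2) overlapped the stricter list of the same library, against 93.6% and 94.8% of shared ones. This is consistent with part of the regions without a partner lying close to the calling threshold. At 1000 bp or more the measure was near its ceiling, with at least 98.5% in every class, and says nothing of broad regions. Regions without a partner were also narrower, with medians of 200 and 175 bp against 375 and 400 bp, and width was not held equal. Of stricter regions, 82.2% and 74.3% overlapped the looser list of the other library. This is little above the 81.6% and 71.9% of looser regions. An effect of the mutation on weakly occupied places stays open, as untested.

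On the X chromosome, fewer stricter regions were missing from the looser list of the same library than on autosomes, with 0.957% against 6.21% in the wild type and 2.15% against 6.88% in K3R3. The reverse measure went the other way, with 13.8% of looser regions on X missing from the stricter list against 10.6% on autosomes in the wild type, and 17.6% against 11.9% in K3R3. The ratio of wild-type to K3R3 covered length on X was 0.988, above the 0.834 to 0.921 of the 17 autosomes other than 6 and 8, whereas the ratio of region counts on X, 0.839, lay within their range of 0.775 to 0.867.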
